A study of Mus musculus with 4 samples.

How the data were processed

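The series holds whole-genome bisulfite sequencing of tail tip DNA from F2 mice, in which bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine to be read as C. There are 4 libraries in 2 groups of 2. One group descends from F1 animals sired with spermatids derived from a source the labels call O-Torgs, an abbreviation they do not expand, and the other from F1 animals sired with in vivo-derived spermatids. The sex of the F1 parents is not given. Each group has 1 library labelled female and 1 labelled male. Groups were taken from the labels, and the replicate numbers were given in accession order. Within each group the 2 libraries differ in sex label, and also in X and Y coverage, so they cannot come from 1 animal. Nothing in the labels says whether the animals come from separate litters. The p-values measure only the spread between these libraries, in which animal, sex and technical differences are mixed. Per the labels' protocols, unmethylated lambda phage DNA was added before conversion, and libraries were made by random priming and amplification.

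Each file lists every covered CpG cytosine, strand by strand. Its coverage column holds counts of the reads over that cytosine, per the file headers, with no normalisation. The deposited methylation values are the percent of those reads that showed C and the percent that showed T. The submitters' processing notes name Trim Galore 0.6.10, Bismark, Picard 2.18.29 and methylKit 1.20.0 and the mouse build mm10; the order of steps and their settings are not given in the sources used here. Methylated calls were recovered as the coverage times the percent of C, rounded to whole calls. A call is 1 read over 1 cytosine, and calls on 1 read pair are not independent, so counting intervals cover counting error only.

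The main values used cytosines with at least 5 reads and at most the 99.9th percentile of coverage of their library (13 to 15 reads). Because the median coverage was 2 reads, values at a minimum of 1 read are given as well. Sequence classes, imprinted intervals and gene lists are described first at 1 read, with values at 5 reads after them, and list members are named at 1 read. Tiles and correlations of window differences are given at 5 reads. A region was tested when it had at least 30 calls and 3 cytosines in every library. Regions were autosomal gene ends, 5-kb windows and 22 imprinted intervals, with X gene ends tested apart. The gene table (GRCm38.p6, the same coordinates as mm10) gives no strand, so promoters could not be placed as planned. In their place stands the end of each protein-coding or lncRNA gene with more CpGs, from 1000 bp outside to 500 bp inside the gene, called a gene end; 32956 of 34328 genes with a unique symbol had one end richer than the other. The imprinted intervals were written down from general knowledge as approximate coordinates before the data were examined, as were 17 gene lists (449 genes), the rule for named genes and the tests.

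Methylated and unmethylated calls were tested with edgeR 4.0.16 (quasi-likelihood test on a methylation design, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05, and differences of at least 10 percentage points were counted apart. Dispersion was estimated within classes of the pooled level, bounded at 10, 30, 70 and 90%. This choice was made after a first fit with a single dispersion had been run on the data and its calls had been seen, because that fit recovered few changed regions of a first simulation. Its counts are kept as an alternative. The simulation was changed at the same time, so the earlier and the present one are not the same test. Its changed regions were then drawn from starting levels under 30 or over 70%, which are easier to detect, and its spread was estimated per class. Regions starting anywhere from 2 to 98% were added back later. Gene lists were tested with camera (limma 3.58.1) on log2 of methylated plus 1 over unmethylated plus 1, with a preset correlation of 0.01, for lists with at least 3 tested members. Single libraries were compared by Fisher's exact test on 1-kb tiles (q under 0.01 and at least 25 points), which compares libraries, not descents. Values per library were compared by two-sided exact permutation tests, which cannot go below p = 0.33 with 2 against 2 libraries. The 4 libraries can be split into pairs in 3 ways: by descent, by sex label, and in the remaining way, called the third split, that was used as a reference. Counting intervals are Wilson intervals at 95%, and the upper limit given for a region without a methylated call is 3 calls over its calls in both libraries. The remaining steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

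The tests were run on simulated data at the real coverages and levels, in which 200 regions were changed in the O-Torgs libraries. With starting levels of 2 to 98% and 5 reads, 4 of 200 gene ends and 0 of 200 windows changed by 40 points were called. At 1 read, 147 of 200 gene ends and 144 of 200 windows changed by 40 points were called, but 5 and 3 of those changed by 20 points. With a single dispersion, 115 gene ends and 126 windows changed by 40 points were called at 1 read. With starting levels under 30 or over 70%, 165 gene ends and 156 windows changed by 40 points were called at 1 read, and 120 and 134 with a single dispersion. Of those changed by 30 points, 92 gene ends and 55 windows were called. At 5 reads, 128 and 180 of those changed by 70 points were called.

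Genes by descent were named where they passed the threshold by at least 10 points in one direction under both sex labels, up to 12 each way, and, where under 10 passed, as the 10 with the smallest p. By sex label the rule took 6 each way, and the 6 with the smallest p were listed where none passed. Called regions outside this rule were named after their values were seen. Every imprinted interval and the 3 members of each list with the largest difference could be named, and 5 windows each way. Alternatives covered the site minimum, the upper coverage limit, a replicate block, limma, the calls a region needs, the extent of gene ends and windows, CpGs whose strands disagree, and leaving out each library. Sequences other than chromosomes 1 to 19, X, Y, the mitochondrial genome and lambda were not used here.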

Results

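Whole-genome bisulfite sequencing was used to compare tail tip DNA methylation of F2 mice descended from F1 animals sired with either O-Torgs-derived or in vivo-derived spermatids. There were 2 libraries per descent, 1 labelled female and 1 labelled male. The O-Torgs libraries held 65281085 calls over 22596344 CpG cytosines (labelled female) and 57117859 calls over 20966641 (labelled male). The in vivo libraries held 59856149 calls over 21532394 cytosines (labelled female) and 60043211 over 21850462 (labelled male). Median coverage was 2 reads per cytosine in every library, and 12.2 to 14.97% of cytosines reached 5 reads. CpG methylation of the unmethylated lambda DNA, the background of the assay, was 0.632% and 0.623% in the O-Torgs libraries and 0.602% and 0.554% in the in vivo libraries, labelled female first. Across 5-kb autosomal windows at a minimum of 1 read, levels correlated between libraries with Pearson r from 0.819 to 0.832, whether or not the pair shared a descent. Windows are not independent replicates.

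The sex labels were examined first, because X inactivation methylates CpG-rich promoters on the inactive X of females. X gene ends were high in 1 library of each descent, and the pair did not share a sex label. At a minimum of 1 read, the median of 506 X gene ends was 39.2% in the O-Torgs library labelled female and 4.51% in the O-Torgs library labelled male, but 5.33% in the in vivo library labelled female and 36.7% in the in vivo library labelled male. Calls per X CpG relative to autosomes were 0.859, 0.450, 0.444 and 0.841 in the same order, and calls per Y CpG were 0.05, 0.473, 0.499 and 0.0624. By sex label, the X gene-end medians were 22.2% ± 23.9 (SD, n = 2) for female and 20.6% ± 22.8 (SD, n = 2) for male, a difference smaller than the spread within each label (exact permutation test, two-sided, p = 0.67). At the minimum of 5 reads only 8 X gene ends could be tested, with medians of 14.9% ± 21.01 and 17.5% ± 21.96 (SD, n = 2 each). The sex of the in vivo libraries is therefore given below only as their label. The third split of the libraries sets the pair with more X coverage against the pair with less. In it edgeR called 361 of the 506 X gene ends at 1 read, 358 of them higher in the first pair. It called 0 by descent and 0 by sex label, where 5 and 4 had an unadjusted p under 0.05. Each descent and each sex label held 1 library with high and 1 with low X gene ends, and the fits had no term for X coverage. These 0 calls therefore do not bear on whether X gene ends differ by descent.

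**Figure D1:**
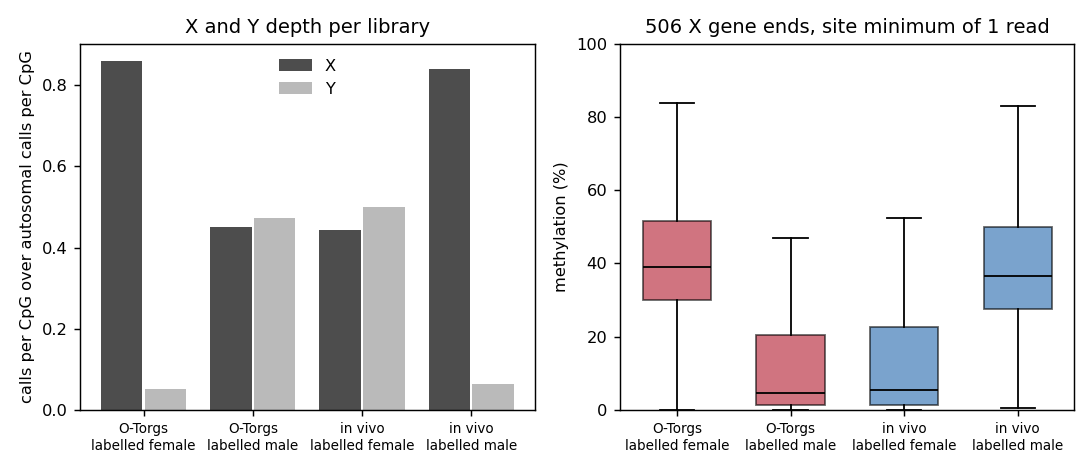
Left, calls per CpG on X and Y over those on autosomes for each library. Right, methylation in percent of 506 X gene ends per library at a minimum of 1 read, with boxes from the lower to the upper quartile, lines at the median and whiskers to the farthest value within 1.5 times the box; the in vivo library labelled female lies with the O-Torgs library labelled male at medians of 5.33% and 4.51%.

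Autosomal methylation was nearly the same in the 2 descents. At a minimum of 5 reads, 68.4% ± 0.086 (SD, n = 2) of calls were methylated in the O-Torgs libraries and 67.7% ± 0.638 (SD, n = 2) in the in vivo libraries, a difference of 0.636 points (exact permutation test, two-sided, p = 0.33, the smallest possible). The lowest library was the in vivo library labelled male at 67.3%, without which the difference was 0.184 points, and without the in vivo library labelled female it was 1.09 points. At a minimum of 1 read the levels were 67.9% ± 0.132 and 68.0% ± 0.268 (SD, n = 2 each), and the difference turned to -0.09 points (exact permutation p = 1). Levels followed CpG density in every library. At 1 read, bins of 1 kb with 60 or more CpGs held 4.55% ± 0.212 in O-Torgs and 4.40% ± 0.107 in in vivo libraries, and bins with under 10 CpGs held 75.1% ± 0.353 and 75.8% ± 0.165 (SD, n = 2 each). Gene bodies outside gene ends were at 70.8% ± 0.159 and 70.9% ± 0.259. Gene ends were at 20.98% ± 0.138 in O-Torgs and 20.5% ± 0.042 in in vivo libraries (SD, n = 2 each), a gap of 0.457 points that was wider at 5 reads, where it was 1.44 points. Both gaps exceeded the SDs, which rest on 2 libraries each, and were not tested. They pool whichever cytosines each library covered, so coverage and methylation are mixed in them. Over gene ends with enough calls in every library, the median difference was 0 points at 5 reads (7278 gene ends). It was -0.0471 points at 1 read (24931 gene ends). These are medians over gene ends and not pooled levels. At 5 reads the gap was 0.533 points in bins with 60 or more CpGs, -0.604 points in those with under 10, and 0.426 points in gene bodies. It was widest in bins with 30 to 59 CpGs, at 47.2% ± 0.102 against 44.2% ± 2.12 (SD, n = 2 each). The gaps in gene bodies and in bins with 30 or more CpGs rested largely on the in vivo library labelled male, at 70.6% in gene bodies, 42.7% in bins with 30 to 59 CpGs and 4.96% in bins with 60 or more. The in vivo library labelled female was at 71.4%, 45.7% and 5.46%, nearer to the O-Torgs means of 71.4%, 47.2% and 5.75%.

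**Figure D2:**
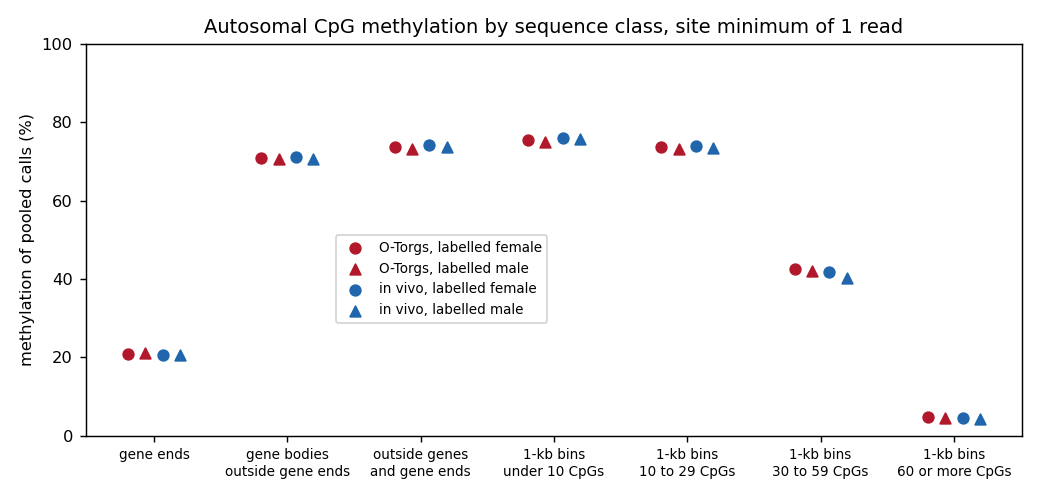
Methylation in percent of pooled autosomal calls by sequence class (horizontal axis) at a minimum of 1 read, with 1 point per library, colour for descent and shape for sex label. Levels ran from 4.32% in the lowest library for bins with 60 or more CpGs to 75.9% in the highest for bins with under 10 CpGs, and the 4 libraries lay close together in each class.

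No autosomal gene end passed the test by descent. At 5 reads, edgeR called 0 of 7278 gene ends, with 141 (1.94%) at an unadjusted p under 0.05, and limma also called 0, with 338 (4.64%). At 1 read edgeR called 0 of 24931, with 994 (3.99%) at an unadjusted p under 0.05. In the simulation of 40-point changes from 2 to 98%, unchanged gene ends had such a p in 1.045% at 5 reads and 4.48% at 1 read (edgeR). The 10 gene ends with the smallest p at 5 reads, none of which passed (adjusted p = 1 for each, edgeR), went in one direction under both sex labels. Picking the smallest p favours such agreement, so it is not separate support. O-Torgs levels were higher at Tex14, which builds the intercellular bridges of germ cells (chromosome 11, 87404013 to 87405513; 90.3% ± 3.15 against 42.0% ± 1.3, SD, n = 2 each), at Gramd2 (71.8% ± 7.98 against 11.99% ± 4.8), at Vwa5b2 (93.9% ± 5.9 against 61.1% ± 7.94), at the imprinted gene Zdbf2 (94.99% ± 1.38 against 73.4% ± 3.65), at the interleukin-6 receptor gene Il6ra (21.2% ± 24.4) and at the potassium channel gene Kcnj12 (4.63% ± 3.45). In vivo libraries had no methylated call at Il6ra and Kcnj12, which allows up to 0.917% of 327 calls and 0.527% of 569 calls. O-Torgs levels were lower at Edem2, of the degradation of misfolded glycoproteins (chromosome 2, 155728975 to 155730475; 44.6% ± 8.74 in in vivo libraries), at Gm15350 (66.7% ± 8.3 against 94.0% ± 0.55), at the ubiquitin-conjugating enzyme gene Ube2k (0.5% against 27.5% ± 8.28) and at the phosphatase gene Pgp (4.72% ± 3.55 in in vivo libraries). O-Torgs libraries had no methylated call at Edem2 and Pgp, which allows up to 2.61% of 115 calls and 0.588% of 510 calls. At 1 read each of these differences except that of Pgp was smaller than at 5 reads, with Tex14 at 2.75 points in place of 48.3 and Gramd2 at 15.1 in place of 59.8. Vwa5b2 stood at 12.3, Zdbf2 at 6.32, Il6ra at 3.5 and Kcnj12 at 0.53 points, and Edem2 at -22.6, Ube2k at -16.99, Gm15350 at -16.3 and Pgp at -5.41 points. Tex14 and Kcnj12 no longer went in one direction under both sex labels. Among the 10 smallest p at 1 read, Popdc2, which is expressed in striated muscle, had 58.7% ± 4.98 against 89.3% ± 6.08 (adjusted p = 0.9999, edgeR), and Ube2k was the gene named under both minimums. At 1 read Ube2k was at 1.83% ± 0.5 against 18.8% ± 19.8 (SD, n = 2 each). Cytosines with 5 reads are among those used at 1 read, so its place under both minimums is not separate support.

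In 5-kb windows, 0 of 96985 were called by descent at 5 reads (edgeR; 3909 at an unadjusted p under 0.05; limma 0, with 4646). With the sex label as a block, 1 window was called at 5 reads, within the proteasome subunit gene Psmc4 (chromosome 7, 28045001 to 28050000). It had 84.0% and 94.9% in the O-Torgs libraries against 47.1% and 57.8% (edgeR adjusted p = 0.0317). This block pairs each in vivo library with the O-Torgs library of opposite X coverage, and no block by X coverage was fitted. With at least 100 calls and 5 cytosines in every library, in place of 30 and 3, 1 of 12355 windows was called, within Gm36509 and higher in O-Torgs libraries (edgeR adjusted p = 0.019). At 1 read, 3 of 374917 were called, all by over 10 points. A window within Snd1, a nuclease subunit of the RNA-induced silencing complex (chromosome 6, 28925001 to 28930000), had 59.3% and 50.3% in the O-Torgs libraries and 88.6% and 91.7% in the in vivo libraries, on 86 to 217 calls (adjusted p = 0.00829, edgeR, n = 2 each). A window within Rasgrp3, a Ras activator (chromosome 17, 75445001 to 75450000), had 46.5% and 62.8% against 89.3% and 89.8% (adjusted p = 0.0197, edgeR). A window 32057 bp from Gm4120 (chromosome 12, 24355001 to 24360000) had 80.9% and 83.3% against 31.6% and 44.8% (adjusted p = 0.0239, edgeR). The sex labels also gave 3 called windows at 1 read and the third split gave 0, or 3 when a single dispersion was used for all levels. The count by descent thus did not exceed that by sex label. Across 96985 windows, the descent difference between the libraries labelled female was set against that between the libraries labelled male, and the 2 were nearly uncorrelated. Pearson r was 0.00954 and Spearman rho 0.00897, beside r = 0.00389 for the sex-label difference in the 2 descents. With the libraries matched by X coverage, r was 0.00563. The differences of the 2 pairs by label had SDs of 14.8 and 15.7 points, and the share of this due to counting was not estimated. So low an r therefore cannot show whether differences by descent recur. Windows are not independent replicates, and no p is given.

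Between single libraries, Fisher's exact test called 2783 of 72308 tiles of 1 kb (3.85%) between the 2 libraries labelled female, 1402 higher in the O-Torgs library and 1381 higher in the in vivo library. It called 2211 of 53723 tiles (4.12%) between the 2 libraries labelled male, 1095 and 1116 of them in those directions. Libraries of the same descent differed as often, in 2428 of 63846 tiles (3.803%) within O-Torgs and 2442 of 61301 (3.98%) within in vivo descent. These counts compare libraries and have no replicate error.

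**Figure D3:**
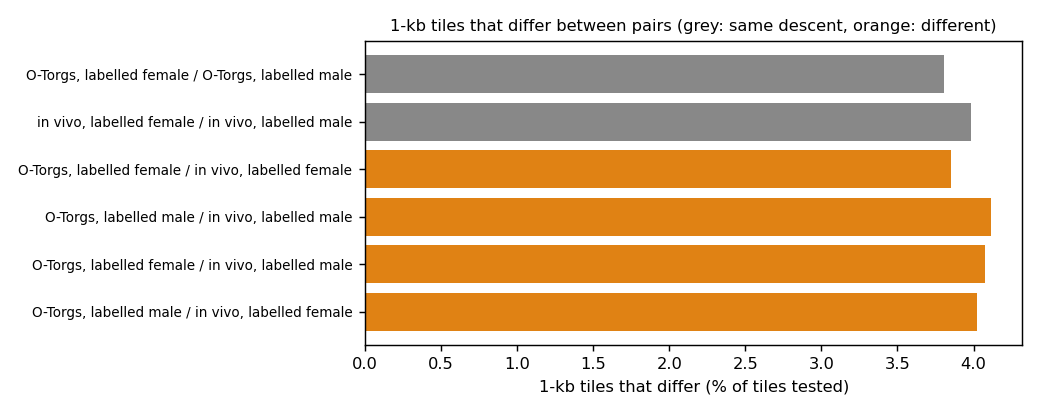
Percent of 1-kb tiles that differed (horizontal axis; q under 0.01 and at least 25 points, Fisher's exact test) for each of the 6 pairs of libraries at a minimum of 5 reads. Pairs of the same descent (grey) at 3.803% and 3.98% and pairs of different descent (orange) at 3.85 to 4.12% overlap.

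Imprinted intervals carry methylation that is set in the germline and differs between the parental copies. At 1 read all 22 intervals lay between 25 and 75% in every library, with medians of 52.7% ± 0.763 in O-Torgs and 51.5% ± 0.245 in in vivo libraries (SD, n = 2 each; exact permutation p = 0.33). At 5 reads the medians over 20 intervals were 56.9% ± 3.88 and 56.4% ± 3.97 (SD, n = 2 each; exact permutation p = 0.67), and 14 of the 20 lay between 25 and 75% in every library. Outside that range were 1 or 2 libraries each at Mcts2-H13 (up to 95.7%), Inpp5f (84.9%), Peg10-Sgce (81.1%), H19 (80.3%), Kcnq1ot1 (79.4%) and Peg3 (78.5%). No interval passed at either minimum, adjusted over the list alone or over all regions (edgeR), with 1 at an unadjusted p under 0.05 each time, and limma called 0 at 5 reads, with 0 at an unadjusted p under 0.05. At 5 reads that was Kcnq1ot1, the control region of the Cdkn1c domain (chromosome 7, 143294001 to 143297000; 74.2% ± 7.41 in O-Torgs against 38.6% ± 1.71; edgeR adjusted p = 0.376, adjusted over the list alone), which stood at 56.8% ± 3.77 against 43.3% ± 11.4 at 1 read. At 1 read it was Slc38a4, an amino acid transporter gene (chromosome 15, 97053001 to 97057000; 44.9% ± 7.55 against 67.5% ± 3.3; edgeR adjusted p = 0.162, adjusted over the list alone). At 1 read, O-Torgs means were also higher by over 10 points at Plagl1 (61.2% ± 1.41 against 47.8% ± 9.57) and at the H19 control region (66.4% ± 10.8 against 53.3% ± 11.2), and lower at Nnat (50.1% ± 2.66 against 61.3% ± 16.3). The remaining intervals differed by under 10 points at 1 read: Nespas-Gnasxl by 8.33, Rasgrf1 by 6.59, Peg13 by 4.85, Inpp5f by 3.34, Zdbf2-Gpr1 by 2.65, Impact by 2.56, Grb10 by 2.28, Zrsr1 by 2.27 and Gnas exon 1A by 0.52 points higher in O-Torgs, and Mcts2-H13 by -0.65, Nap1l5 by -2.71, Snrpn by -3.72, Peg3 by -3.97, Airn-Igf2r by -4.74, Peg10-Sgce by -5.2, Dlk1-Meg3 by -7.69 and Mest by -7.79 points. At 5 reads 9 of 20 intervals differed by at least 10 points: Kcnq1ot1 by 35.6, H19 by 31.99, Rasgrf1 by 23.9, Plagl1 by 12.6 and Grb10 by 10.4 points higher in O-Torgs, and Peg10-Sgce by -22.1, Peg3 by -19.7, Dlk1-Meg3 by -14.2 and Inpp5f by -13.5 points. The rest lay between -8.9 points at Mest and 4.26 points at Zdbf2-Gpr1. Inpp5f, Gnas exon 1A (-7.56), Impact (-1.87) and Nespas-Gnasxl (-0.66) had the opposite sign at the 2 minimums. Imprinted intervals were not simulated, so the size of difference that their test could call is not known.

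**Figure D4:**
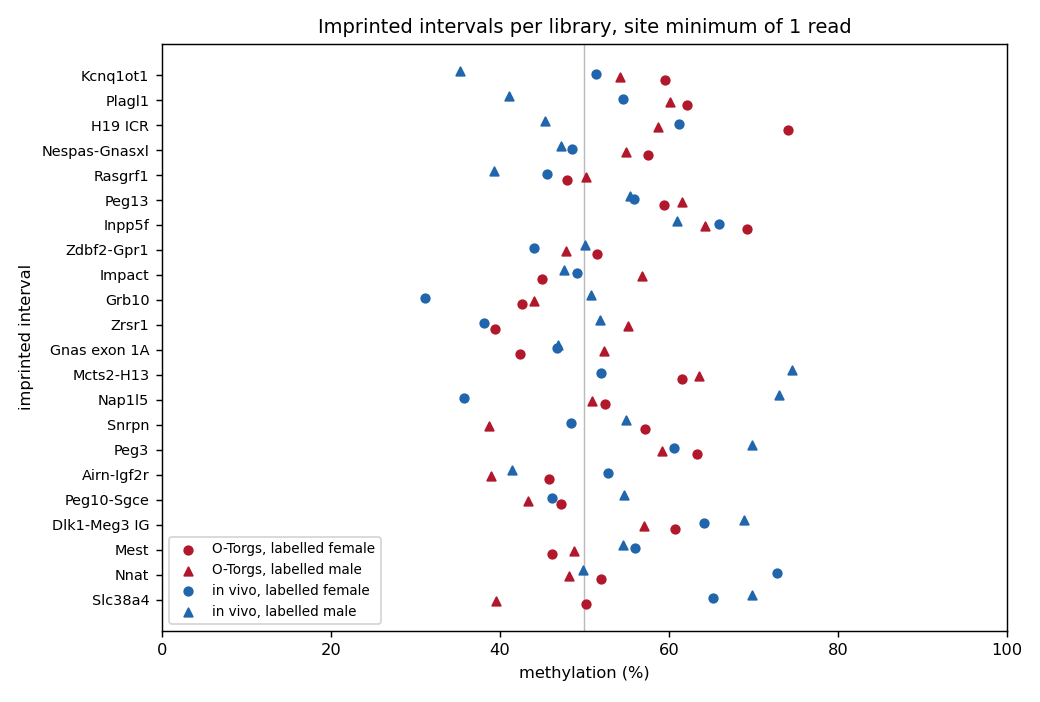
Methylation in percent (horizontal axis) of 22 imprinted intervals at a minimum of 1 read, with 1 point per library, colour for descent and shape for sex label, ordered by the difference between descents. All points lie between 25 and 75%, and the widest gap is that of Slc38a4 at -22.7 points.

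None of the gene lists was called by descent with camera, at 5 reads (13 lists with at least 3 members tested, smallest adjusted p = 0.747) or at 1 read (17 lists, smallest adjusted p = 0.829); no list had an unadjusted p under 0.05. With an estimated correlation the smallest adjusted p was 0.918 and 0.885, and fry gave 0.543 and 0.816. At 1 read, germline genes, which promoter methylation keeps silent in somatic tissue, were at a median of 80.5% ± 0.42 in O-Torgs and 77.8% ± 0.58 in in vivo libraries (SD, n = 2 each), 27 members higher and 17 lower. Their largest differences were at Sohlh1 (70.8% ± 8.34 against 51.2% ± 9.22), at the RNA helicase gene Ddx4 (79.8% ± 10.9 against 66.6% ± 10.9) and at the meiotic cohesin gene Rec8 (44.3% ± 40.1 against 32.8% ± 9.72). Spermatid genes were at 66.5% ± 9.22 and 71.6% ± 0.83, 11 higher and 18 lower, with the transition protein gene Tnp2 at 59.6% ± 1.75 against 76.7% ± 4.48. Ldhc, the lactate dehydrogenase of male germ cells, was at 41.1% ± 13.4 against 57.97% ± 2.88. Pluripotency and 2-cell genes were at 38.8% ± 2.02 and 47.8% ± 12.1, 9 higher and 8 lower, with Esrrb at 35.4% ± 6.78 against 55.7% ± 23.3. Clustered protocadherins were at 30.02% ± 5.28 and 25.9% ± 4.69, 28 higher and 17 lower, with Pcdhb8 at 37.7% ± 6.21 against 64.8% ± 7.34. Homeobox cluster genes were at 11.2% ± 2.65 and 8.2% ± 1.18, 21 higher and 17 lower, with Hoxd4 at 35.2% ± 4.13 against 15.7% ± 2.22. Hoxa6 was at 38.7% ± 0.0495 against 51.5% ± 1.82. The DNA methylation machinery was at 4.11% ± 0.61 and 3.47% ± 0.08, 13 higher and 12 lower, with Dnmt3l, the cofactor of germline methylation, at 86.5% ± 7.08 against 78.7% ± 4.64.

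Gene ends of maternally methylated imprinted genes were at 48.5% ± 3.77 in O-Torgs and 46.7% ± 9.05 in in vivo libraries (SD, n = 2 each, 1 read), 12 higher and 10 lower, with Slc38a4 at 40.2% ± 2.4 against 66.2% ± 8.71. Kcnq1ot1 was at 63.4% ± 3.34 against 39.6% ± 0.834. At 5 reads Zdbf2 was the 1 member of any list that passed when adjusted over the list alone (edgeR adjusted p = 0.0379). Each list was adjusted separately. The Zdbf2-Gpr1 imprinted interval (chromosome 1, 63255001 to 63268000) was at 48.5% ± 1.17 against 44.3% ± 2.57 at 5 reads. The gene end of Zdbf2 (63199358 to 63200858) lies outside that interval and was at 94.99% ± 1.38 against 73.4% ± 3.65. It did not pass over all gene ends (edgeR adjusted p = 1). At 1 read its difference was 6.32 points, and no member of any list passed. Other imprinted genes were at 15.3% ± 0.15 and 20.1% ± 6.92, 10 higher and 13 lower, with Meg3 at 35.6% ± 28.9 against 59.6% ± 1.21. Housekeeping genes were at 1.98% ± 0.39 and 2.12% ± 0.51, 10 higher and 14 lower, with Chmp2a at 29.2% ± 2.23 against 18.7% ± 12.3. Growth regulators were at 4.58% ± 0.73 and 3.93% ± 0.23, 19 higher and 10 lower, with the leptin gene Lep at 52.9% ± 12.7 against 66.7% ± 13.3.

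At 5 reads, with fewer members tested, the list medians in O-Torgs and in vivo libraries (SD, n = 2 each) were as follows. Germline genes were at 85.7% ± 4.52 and 82.05% ± 1.56, 8 members higher and 9 lower, and spermatid genes at 20.6% ± 8.33 and 32.3% ± 6.27, 2 higher and 5 lower. Pluripotency and 2-cell genes were at 2.1% ± 1.7 and 1.05% ± 0.85, homeobox cluster genes at 3.9% ± 1.18 and 4.33% ± 1.69, and clustered protocadherins at 15% ± 13.8 and 23.2% ± 10.9. Only 3 pluripotency and 2-cell genes and 3 protocadherins were tested here, against 17 and 45 at 1 read. Medians at the 2 minimums thus cover different genes. The methylation machinery was at 0.89% ± 0.29 and 1.09% ± 0.47, housekeeping genes at 0.34% ± 0.49 and 1.54% ± 1.04, and growth regulators at 0.68% ± 0.96 and 2.01% ± 0.53. Maternally methylated imprinted genes were at 47.3% ± 1.1 and 49.3% ± 12.5, 6 higher and 3 lower. Other imprinted genes were at 6.86% ± 0.14 and 16.6% ± 1.48, 2 higher and 8 lower, a gap beyond the SDs that did not pass the test (camera of limma, adjusted p = 0.747). Medians and the camera direction differed in sign at 5 reads for maternally methylated imprinted genes and clustered protocadherins (lower medians in O-Torgs, direction up). The median of the members' differences was below 0 for germline genes, with direction up, and above 0 for cartilage and bone markers, with direction down.

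Markers of the cell types that a tail tip can hold did not pass the test by descent at either minimum (camera). At 5 reads keratinocyte markers were at 0.48% ± 0.29 in O-Torgs and 3.45% ± 0.62 in in vivo libraries (SD, n = 2 each), 0 of 5 members higher and 5 lower, a gap beyond the SDs (camera of limma, adjusted p = 0.747). Fibroblast markers were at 4.69% ± 3.7 and 5.43% ± 1.25, 0 of 4 higher and 4 lower (camera of limma, adjusted p = 0.917), and cartilage and bone markers at 7.04% ± 5.62 and 8.72% ± 6.43. The remaining marker lists had under 3 members tested at 5 reads. At 1 read, median gene-end levels in O-Torgs and in vivo libraries (SD, n = 2 each) were 17.1% ± 5.44 and 11.5% ± 3.92 for keratinocyte markers, the opposite order, with the laminin gene Lama3 at 35.3% ± 8.06 against 13.6% ± 9.21. They were 7.69% ± 0.8 and 8.1% ± 2.06 for fibroblast markers, with Col1a1 at 33.0% ± 4.76 against 17.5% ± 8.1. Cartilage and bone markers were at 37.0% ± 2.54 and 37.6% ± 5.75, with Col9a1 at 77.4% ± 9.59 against 87.9% ± 2.1. Skeletal muscle markers were at 18.8% ± 0.49 and 19.2% ± 0.36, with Tnnt3 at 64.2% ± 11.4 against 47.9% ± 13.8. Blood cell markers were at 72.8% ± 1.44 and 71.9% ± 3.3, with Itgam at 63.9% ± 30.2 against 80.8% ± 1.72. Endothelial markers were at 65.2% ± 4.26 and 68.2% ± 0.09, with Tek at 54.1% ± 7.45 against 36.0% ± 17.5. Neural and glial markers were at 7.11% ± 1.64 and 8.0% ± 0.77, with the myelin gene Pmp22 at 76.6% ± 10.4 against 86.7% ± 3.55. At 1 read, medians and the camera direction differed in sign for keratinocyte markers (higher medians in O-Torgs, direction down) and fibroblast markers (lower medians, direction up). For cartilage and bone, skeletal muscle, and pluripotency and 2-cell genes, the median of the members' differences was above 0 and the direction down.

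By sex label, which the X coverage of the in vivo libraries goes against, no autosomal gene end was called at 5 reads (0 of 7278, edgeR; 165 at an unadjusted p under 0.05; limma 0, with 381) or at 1 read (0 of 24931; 1056). The gene end with the smallest p at 1 read was Gm43305, at 29.4% and 51.0% in the libraries labelled female and 94.0% and 89.2% in those labelled male (adjusted p = 0.0586, edgeR, n = 2 each). Ecm1, an extracellular matrix gene, was among the 6 smallest p at both minimums, at 45.6% and 60.2% against 84.9% and 90.3% at 1 read (adjusted p = 0.823, edgeR). No window was called at 5 reads (0 of 96985; 3795 at an unadjusted p under 0.05; limma 0, with 4563), and 3 of 374917 were called at 1 read. With descent as a block, 3 windows were called at 5 reads, within Dhx35, Keap1 and Gm32663 (smallest edgeR adjusted p = 0.000865). Without the in vivo library labelled male, 4 windows and 1 gene end, that of Zzz3, were called at 5 reads. A window within Pik3c3, a lipid kinase gene of autophagy (chromosome 18, 30265001 to 30270000), had 54.1% and 31.4% in the libraries labelled female and 85.9% and 88.5% in those labelled male (adjusted p = 5.24e-05, edgeR, n = 2 each). A window within the centrosomal gene Cep85 (chromosome 4, 134160001 to 134165000) had 22.3% and 38.04% against 85.0% and 68.4% (adjusted p = 0.000513, edgeR). A window 2775 bp from Gm40469 (chromosome 8, 20555001 to 20560000) had 69.5% and 66.4% against 27.2% and 26.7% (adjusted p = 0.00173, edgeR).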

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

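The tests of explanations in this part were chosen after the result was seen, except that of the share of mitochondrial calls held by few sites; the counts of regions called by descent, by sex label and, for windows, in the third split, with the limma, block, call minimum and 1-read alternatives, were planned.

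The in vivo library labelled female had Y coverage of 0.499 of its autosomal depth, against 0.05 in the O-Torgs library labelled female, in a sequence that no comparison used. The Y depth was 9.98 times that of the O-Torgs library labelled female, which argues against an animal with 1 X and no Y, and 1.05 times (1.055) that of the O-Torgs library labelled male, which argues against an admixture of DNA of the other sex. In X depth, Y depth and X gene ends, each in vivo library lay within 1.25 times (1.248) of the O-Torgs library of the other label. The values are consistent with an exchange of the 2 in vivo libraries, files or sex labels, and the data do not show at which step. An exchange within the in vivo group leaves the fits by descent without a block as they are and mixes the comparison by sex label. It changes what pairs the descents by label: the block, the correlation of window differences and the direction under both sex labels. A rearrangement of more than 2 libraries across the descents could give the same X and Y pattern. It would mix the descents and was not tested.

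At a minimum of 1 read, 361 of 506 X gene ends were called in the third split of the 4 libraries (edgeR), which sets the descent difference under one sex label against that under the other. This split is also the one by X coverage, and the fit had no terms for descent or sex label.

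Mitochondrial CpG methylation was 1.67% (Wilson interval 1.53 to 1.81%) in the in vivo library labelled male, above the 0.554% of its lambda DNA, and 0.731% (0.638 to 0.837%) in the in vivo library labelled female, above its 0.602%; the O-Torgs libraries had 0.542% (0.468 to 0.629%) and 0.552% (0.472 to 0.645%), with intervals that overlap those of their lambda levels. Incomplete conversion of the library as a whole is argued against by its lambda level of 0.554%, the lowest of the 4 libraries. The lambda level does not measure conversion of the mitochondrial DNA itself, so incomplete conversion limited to it stays open. A few sites as the source are argued against because the 10 sites with most methylated calls held 13.9% of them, spread over 203 sites. The bound set beforehand concerned sites alone and no molecules were counted, so a few molecules with many methylated calls stay open. Reads from nuclear copies of mitochondrial DNA were not tested and stay open, as does a difference between the animals.

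No autosomal region was called by descent at a minimum of 5 reads with at least 30 calls and 3 cytosines and no block (edgeR; 141 gene ends and 3909 windows at an unadjusted p under 0.05; limma 0), but 1 window was called with at least 100 calls and 5 cytosines (Gm36509), 1 with the sex label as block (Psmc4) and 3 at 1 read. Between the libraries with more and with less X coverage, 71.3% of X gene ends were called at 1 read, where the median X difference was 26.4 points, but these were adjusted over 506 X gene ends alone and do not bear on autosomes. In simulated data at 1 read 72% of windows changed by 40 points were called, but 55 of 200 changed by 30 points (starting levels under 30 or over 70%) and 3 of 200 changed by 20 points, so changes of such sizes stay open. The percent of windows with an unadjusted p under 0.05 was 4.86% by descent, 4.56% by sex label and 4.50% in the third split, so differences by descent and between libraries of either descent cannot be told apart, since 4 libraries allow only 3 splits.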

How the results depend on the processing

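A single dispersion, the CpG-poorer gene end, 10-kb windows at 1 read, cytosines common to all libraries at 1 read, runs of CpGs, the block and other list tests at 1 read, and other pairings of libraries were chosen after seeing the data; regions named here were chosen after their values were seen. Gene ends by descent, imprinted intervals and gene lists had 0 calls under every alternative run. This says little at 5 reads, where simulated changes of 40 points were mostly missed. At 1 read it says little about smaller changes. There, 5 of 200 gene ends changed by 20 points were called (starting levels of 2 to 98%). Imprinted intervals and gene lists were not simulated. The global difference of 0.636 points moved to -0.09 at 1 read, -0.13 at cytosines covered in all 4 libraries, -0.138 at such cytosines at 1 read, and 1.63 (1.629) at 10 reads, and ranged from 0.184 to 1.09 with each library left out; the cause was not tested. The imprinted median difference became -4.63 (-4.625) at 10 reads, where 1 interval was left, and ranged from -2.34 to 3.76 with each library left out. Windows by descent went from 0 to 3 at 1 read (3 with a single dispersion, the same windows, when the third split also gave 3: Chd9, H2ac23 and Gm52006), 3 others in 10-kb windows at 1 read (Rbm39, Iqgap2 and near Gm19600), 1 with at least 100 calls and 5 cytosines (Gm36509) and 1 with the replicate block (Psmc4). Windows by sex label went to 3 at 1 read (3 with a single dispersion), 2 in 10-kb windows at 1 read (0 in those at 5 reads), 1 without an upper coverage limit (AY036118), 3 with the replicate block (Dhx35, Keap1 and Gm32663) and 0 to 4 with each library left out, the 4 (Celsr2, 4932438H23Rik, and near Gm52814 and A530076I17Rik) without the in vivo library labelled male. Gene ends by sex label went to 1 without an upper limit (AY036118) and 0 to 1 with each library left out (Zzz3, without that same library). The number of each library goes with its sex label, so the replicate block is the sex label in the fit by descent and descent in the fit by sex label; it changed no other call, and same-numbered libraries deviated across windows with r = 0.00389. The X gene-end difference by label ranged from -17.5 to 24.9 points with each library left out, as the conflict between labels and X coverage gives. Tiles between the libraries labelled female went from 2783 of 72308 (3.85%) to 6794 of 474134 (1.43%) at 1 read. They were 95 of 2373 (4.003%) at 10 reads and 6679 of 72308 (9.24%) at q under 0.05 and 10 points. Tiles between those labelled male went from 2211 of 53723 (4.12%) to 6924 of 430232 (1.61%) at 1 read. They were 52 of 1205 (4.32%) at 10 reads and 5253 of 53723 (9.78%) at the other threshold. At 1 read the counts thus rose while the shares fell. Pairs of the same descent then differed in 1.46% (O-Torgs) and 1.54% (in vivo) of tiles. Gene lists and X gene ends gave no value at 10 reads. Removing CpGs with discordant strands, planned against sequence variants, cannot remove those that change a CpG on both strands. At 5 reads, 12.2 to 14.97% of cytosines were used. In a fit without 1 library, the lone library of its group is assumed to vary like the others.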

Other observations

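The test of genes that escape X inactivation was written before its result was seen; the remaining values were singled out after they were seen.

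Most X gene ends that were low in the pair of libraries with less X coverage were higher in the pair with more, by a median of 30.1 points over 354 gene ends at a minimum of 1 read. A hypothesis was that genes known to escape X inactivation are less methylated there than other X genes. Of 6 such genes written down beforehand, 4 could be tested: the RNA helicase gene Ddx3x (2.74% and 2.22% in the pair with more X coverage, 2.33% and 0% in the other), Eif2s3x (0.61% and 0.47%, 0% and 0%), Pbdc1 (2.19% and 3.61%, 0% and 5.71%) and the histone demethylase gene Kdm5c (0% and 0.85%, 1.2% and 0%). Their median difference was 0.29 points, and 0 of 10000 random lists of 4 such gene ends had a median as low, so these data are in line with the hypothesis that genes known to escape X inactivation stay unmethylated in the libraries with high X coverage.

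With no upper coverage limit, the gene end of AY036118 on chromosome 17 (39847112 to 39848612) rested on 36795 to 52897 calls per library. Its level was 12.3% and 12.1% in the libraries labelled female and 28.6% and 32.9% in those labelled male (adjusted p = 0.00111, edgeR, n = 2 each), and so followed the sex label and not the X coverage. Its depth is far above that of a single-copy region. One autosomal gene end, that of the histone gene H4c17 on chromosome 13, was called in the third split at 1 read, at 31.7% and 29.6% in the pair with more X coverage and 0% and 1.56% in the other (adjusted p = 0.0316, edgeR, n = 2 each). With a single dispersion for all levels it was not called (edgeR, 0 of 24931 gene ends, smallest adjusted p = 0.12, with 1065 at an unadjusted p under 0.05). The 5-kb window that holds this gene end (21810001 to 21815000, given above as H2ac23) was called with a single dispersion at 1 read (adjusted p = 0.0215, edgeR). It was at 32.35% and 30.14% in the pair with more X coverage and 6.12% and 5.41% in the other.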
